A study of Anopheles gambiae with 6 samples.

How the data were processed

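The series holds 6 one-colour Affymetrix oligonucleotide arrays of Anopheles gambiae midgut RNA, 3 for each of 2 meals. Per the labels' protocols, biotin-labelled cRNA was made from 5 ug of total RNA with a labelling method primed at the 3' end of transcripts, and each array read a separate pool of 10 midguts. The deposited values are intensities: 1 positive MAS5 signal per probe set on a linear scale, with MAS5 named in the submitters' processing notes. The MAS5 version, its scaling target and any detection call are not given in the sources used here. The values were checked before use. They ran from 0.7 to 85423 with 1 decimal, no probe set was repeated or missing, and the 2% trimmed mean of the arrays lay between 206.2 and 216.7, so the scaling of the authors was kept and no further normalization was applied. No column of the table went unused (0 unused columns).

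The table has 16898 probe sets: 16884 whose IDs start with Ag, 8 named by a sequence accession and 6 Affymetrix control probe sets for actin and Gapdh. Neither the table nor the reference gene table used here (assembly idAnoGambNW_F1_1, 15165 genes) pairs these IDs with genes, and 0 IDs matched any identifier in it. Probe sets are therefore reported by ID, and no gene name, function or genome position is given for them. The 36 gene lists (immune pathways, digestion, stress, metabolism and markers of other cell types in a dissected gut) that were fixed before the data were examined could not be applied, so the gene set tests planned with them were not run. The plan to read background from Plasmodium probe sets could not be followed either, because the table used here has none. The fallback fixed with it was used: a probe set was tested when its mean log2 signal over the 6 arrays exceeded the 40th percentile of all probe sets, a signal of 39.8. This kept 10133 probe sets, and the 6 control probe sets and 6759 dimmer probe sets were left out.

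The comparison was the meal with heat-killed E. coli against the meal without, with 3 pools in each group taken from the titles. Log2 signals, with no pseudocount, were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend on mean signal), and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. Each pool was a separate set of midguts, so the p-values rest on the spread between pools. The variance of each probe set was drawn towards that of probe sets of like signal, with 9.66 prior against 4 residual degrees of freedom. Most of its weight thus came from other probe sets. The p-values do not measure spread between separate rearings, which the labels do not describe. Control ratios were compared with two-sided exact permutation tests, whose smallest possible p for 3 against 3 arrays is 0.1.

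The planned rule for named items asked for a gene symbol or description, which no probe set has. The same ranking was kept without that condition and shortened to the 2 largest rises and the 2 largest falls among probe sets past the threshold whose 2 groups did not overlap. The number of arrays limits the precision. The median half-width of the 95% confidence interval of a log2 fold change was 0.64 in the brightest tertile of tested probe sets, 1.15 in the middle tertile and 2.01 in the dimmest. The fit was run on simulated data: 5 simulations of the 10133 probe sets with 200 changed in each. Simulated values were independent and normal, with variances drawn from the variance model that the fit gave for these arrays. The fit recovered 4% of 2-fold changes, 36.4% of 4-fold changes, 59.6% of 8-fold changes and 70% of 16-fold changes, and 5.35% of its calls were false. The simulation took that variance model as true and held no array shift shared across probe sets. Its shares are therefore no test of the model. Alternatives fixed beforehand were no filter, quantile normalization, median centring, the replicate number as a block, no variance trend, no moderation of the variance, and leaving out each array. Stricter filters, pseudocounts of 16 and 64 and a signal floor were added after seeing the data.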

Results

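The transcriptome of the midgut of Anopheles gambiae, the main African malaria mosquito, was profiled 3 h after an artificial protein meal. Mosquitoes of the G3 laboratory strain, 5 to 6 days old, had taken 20% bovine serum albumin (BSA) in buffered saline with 10 mM bicarbonate, either alone or with heat-killed Escherichia coli, a Gram-negative bacterium. Each meal was represented by 3 arrays, and each array by a pool of 10 midguts. The arrays read 16898 probe sets. The median MAS5 signal was 68.2, 74.1 and 79.9 on BSA replicates 1, 2 and 3, and 68.7, 76.4 and 78.7 on E. coli replicates 1, 2 and 3. Among the 10133 probe sets bright enough to test, Pearson correlations of log2 signal lay between 0.80 and 0.82 for the 3 pairs of BSA arrays and between 0.81 and 0.85 for the 3 pairs of E. coli arrays. The 9 pairs across meals lay between 0.77 and 0.83. Among probe sets with a geometric mean signal above 256, BSA replicate 3 correlated at 0.954 and 0.936 with E. coli replicates 2 and 3. It correlated at 0.928 and 0.927 with BSA replicates 1 and 2, and at 0.917 with E. coli replicate 1. E. coli replicate 2 correlated at 0.931 and 0.924 with BSA replicates 1 and 2. With E. coli replicates 1 and 3 it correlated at 0.912 and 0.952, and those 2 arrays correlated at 0.895 with each other. These correlations run across probe sets, which are not independent replicates.

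The control probe sets for actin, a cytoskeletal protein, and Gapdh, a glycolytic enzyme, were examined first, since they are the only features that the table names by gene. Actin was among the bright signals with either meal. Its 3' probe set read 36402 ± 1376 (SD, n = 3) after BSA and 32817 ± 8770 (SD, n = 3) after BSA with E. coli, a log2 difference of -0.19 (two-sided exact permutation p = 0.8). The Gapdh 3' probe set read 11028 ± 3265 (SD, n = 3) after BSA and 7866 ± 566 (SD, n = 3) with E. coli, a log2 difference of -0.44 (two-sided exact permutation p = 0.3). For both genes the difference was within the spread between pools, and across the 6 control measures compared every Benjamini-Hochberg adjusted p was 0.9.

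The ratio of the 3' to the 5' control probe set falls when labelled cRNA reaches further towards the 5' end of the transcript. For actin it was 90.8, 73.8 and 108.4 on BSA replicates 1, 2 and 3. E. coli replicates 2 and 3 read 124.9 and 105.1, whereas E. coli replicate 1 read 30.2. For Gapdh, E. coli replicate 1 was again the lowest array at 22.2, and E. coli replicate 3 was the highest at 296.7, with E. coli replicate 2 at 42.0. BSA replicate 3 read 47.9, against 92.0 and 94.9 on BSA replicates 1 and 2, and its Gapdh 3' signal of 7450 was inside the range of the E. coli arrays (7299 to 8432), against 11790 and 13844 on the other BSA arrays. Neither ratio separated the meals (two-sided exact permutation p = 0.9 for actin and 0.9 for Gapdh), in a test that cannot give a p below 0.1. On all 6 arrays the 3' control signal was at least 22.2 times the 5' signal, so strong 3' bias was common to both meals. The Gapdh ratio of 296.7 rests on a 5' signal of 24.6, under the filter signal of 39.8.

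**Figure D1:**
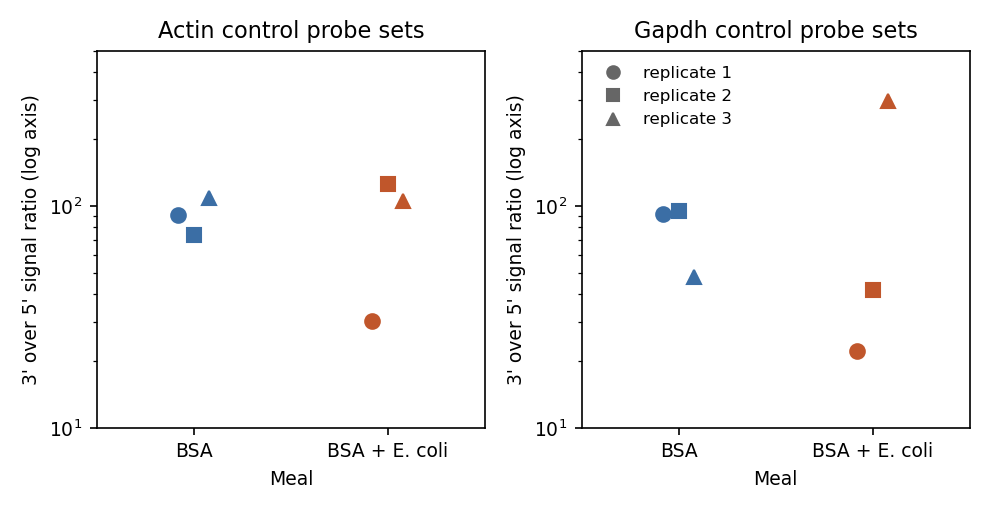
Ratio of 3' to 5' MAS5 signal (log axis) of the actin (left) and Gapdh (right) control probe sets on each of the 6 arrays, by meal, with the marker shape giving the replicate number. E. coli replicate 1 is the lowest array in both panels, at 30.2 for actin and 22.2 for Gapdh.

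The comparison of the 2 meals asked which midgut transcripts differ when a protein meal carries bacteria. With E. coli in the meal, 7 of the 10133 tested probe sets changed (limma, adjusted p below 0.05), 4 of them higher and 3 lower. All 7 changes were at least 3.16-fold, and in each the 3 arrays of one meal lay wholly above the 3 of the other. Of the 7 changes, 6 were in the brightest tertile of tested probe sets, 1 was in the middle tertile and 0 were in the dimmest. In the dimmest tertile the median 95% interval spans 2.01 either side of the log2 fold change, so changes of moderate size were not detectable there. The median log2 fold change of all tested probe sets was 0.04. At the 134 probe sets with a mean signal above 10000 the median was -0.28, and 115 of the 134 had a lower mean log2 signal with E. coli. Quantile normalization, which gives all arrays the same highest values by construction, brought the median to -0.07.

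The largest rise was at Ag.2R.2566.0_CDS_at, which went from a signal of 42.4 ± 33.0 (SD, n = 3) after BSA to 1337 ± 983 (SD, n = 3) with E. coli. Its log2 fold change was 4.98 with a standard error of 0.58 (limma, adjusted p = 0.0024). The 3 BSA arrays read 22.2, 24.5 and 80.5, close to the signal of 39.8 at which probe sets were admitted to the test, and the 3 E. coli arrays read 569.2, 2444.9 and 996.5. With the BSA side this dim, the size of the rise depended on how low signals were treated: the log2 fold change was 4.42 with a pseudocount of 16, 4.47 with signals floored at 39.8 and 3.53 with a pseudocount of 64, settings chosen after seeing the data. The second rise, at Ag.2L.205.0_CDS_at, was from 246.2 ± 193.4 to 1523 ± 529 (SD, n = 3 for each), a log2 fold change of 2.83 with a standard error of 0.44 (limma, adjusted p = 0.027). BSA replicate 3 read 469.2 at this probe set, against 124.4 and 144.9 on the other BSA arrays. The other 2 rises had log2 fold changes of 2.52 and 1.66 (limma, adjusted p = 0.0011 and 0.018). The first of these, a rise from 1203 ± 270 to 6876 ± 1429 (SD, n = 3 for each), had the smallest p-value of all. Its ID ends in _s_at, the array maker's mark for a probe set that can read more than 1 transcript. The partner probe set with the same ID number and no such mark had a log2 difference of -0.14 with a standard error of 0.34 (limma, adjusted p = 0.94).

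The largest fall was at Ag.3R.578.1_CDS_a_at, from 1786 ± 546 after BSA to 128.3 ± 108.4 with E. coli (SD, n = 3 for each). The log2 fold change was -4.07 with a standard error of 0.47 (limma, adjusted p = 0.0024), and -3.36 with a pseudocount of 64. Ag.3R.795.0_CDS_at fell from 1971 ± 927 to 345.2 ± 93.5 (SD, n = 3 for each), a log2 fold change of -2.45 with a standard error of 0.33 (limma, adjusted p = 0.0091). The remaining fall was smaller, from 3465 ± 708 to 1043 ± 244 (SD, n = 3 for each), with a log2 fold change of -1.74 and a standard error of 0.25 (limma, adjusted p = 0.015). At all 3 falls BSA replicate 3 was the BSA array nearest to the E. coli arrays, reading 1194.1, 1281.8 and 2743.8 in the order given.

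**Figure D2:**
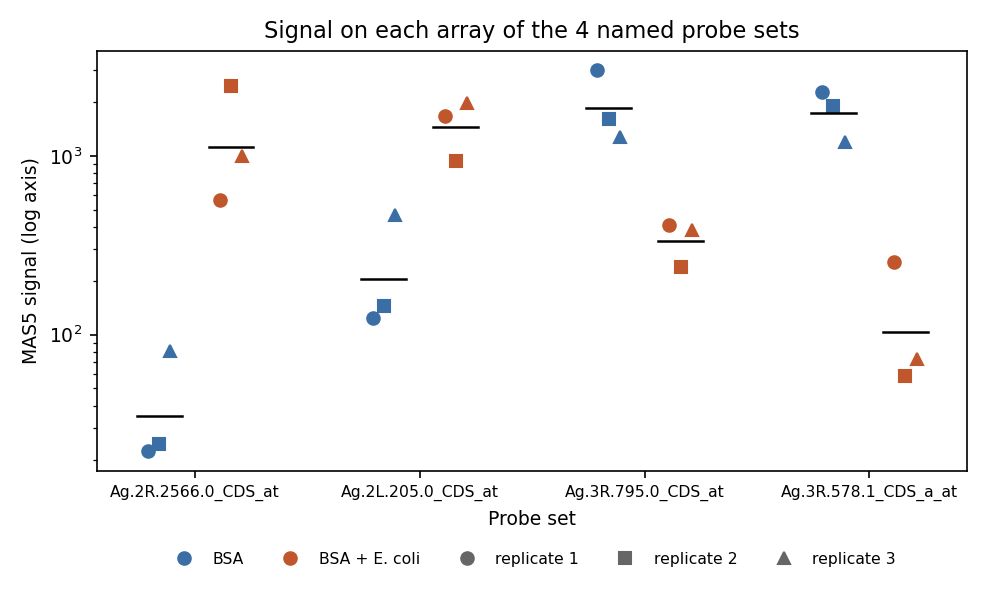
MAS5 signal (log axis) of the 2 probe sets with the largest rise and the 2 with the largest fall, on each of the 6 arrays, with colour for the meal, marker shape for the replicate number and a black bar at the geometric mean of each group. The 2 meals do not overlap at any of the 4 probe sets, and BSA replicate 3 is the BSA array closest to the E. coli arrays at each.

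A further 9 probe sets with a mean signal above 256 had a geometric mean signal at least 8-fold higher with E. coli and did not pass the adjusted test. At 8 of the 9 some BSA signal lay under 39.8, so the size of the fold is uncertain: with signals floored at 39.8, a setting chosen after seeing the data, 9 were still at least 8-fold higher, while the ratio of arithmetic mean signals was 3.94 to 8.02. The groups overlapped at 3 of the 9. In 9 of these 9 the highest of the BSA arrays was BSA replicate 3, and 9 passed when that array was left out. No probe set (0) of that signal had a fall of this size without passing.

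Counting the 7 that passed the adjusted test, 531 probe sets were higher and 313 were lower with E. coli at an unadjusted p under 0.05 (limma). The total was 844, where 507 would be expected by chance alone. The groups did not overlap at 1381 probe sets, or 13.6% of those tested, where chance gives 10%. Of these 1381, 404 were at least 2-fold higher with E. coli and 222 at least 2-fold lower. The balance of 531 higher and 313 lower at an unadjusted p under 0.05 moved with the arrays included. Without E. coli replicate 1, the array with the lowest 3' to 5' control ratios, 391 were higher and 445 lower, and without E. coli replicate 2 the counts were 432 and 384. Without BSA replicate 1 they were 453 and 164, and without BSA replicate 2 they were 415 and 135. They were 742 and 379 without BSA replicate 3, and 339 and 242 without E. coli replicate 3. Median centring of the arrays gave 428 higher and 341 lower.

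**Figure D3:**
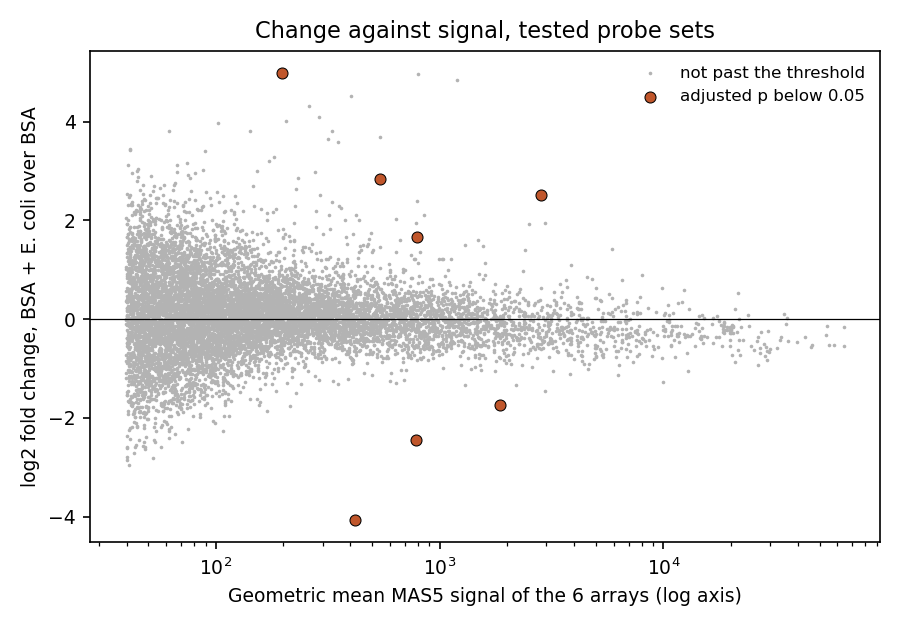
Log2 fold change (BSA with E. coli over BSA) against the geometric mean MAS5 signal of the 6 arrays (log axis) for the 10133 tested probe sets, with the 7 past the adjusted threshold in colour. The scatter of grey points widens towards low signal, and 6 of the 7 coloured points lie in the brightest tertile.

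The number of changed probe sets depended on single arrays and on how the spread was estimated. Without BSA replicate 3, 105 probe sets passed (91 higher, 14 lower), including all 7, while leaving out another array gave 4 without BSA replicate 1, 4 without BSA replicate 2, 9 without E. coli replicate 1, 2 without E. coli replicate 2 and 4 without E. coli replicate 3. The fall at Ag.3R.578.1_CDS_a_at passed without any 1 of the 6 arrays. The rise at Ag.2R.2566.0_CDS_at did not pass without E. coli replicate 2 (limma, adjusted p = 0.057). The fall at Ag.3R.795.0_CDS_at did not pass without BSA replicate 1 or E. coli replicate 2 (limma, adjusted p = 0.057 for each). The rise at Ag.2L.205.0_CDS_at passed when BSA replicate 3 was the array left out, where its log2 fold change was 3.44, and had adjusted p from 0.057 to 0.30 without any other array (limma). It did not pass after quantile normalization either (limma, adjusted p = 0.060). With the replicate number as a block, a pairing that the labels do not explain, 79 passed (63 higher, 16 lower), including all 7. With no trend of variance on signal, limma called 0 probe sets (665 at an unadjusted p under 0.05).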

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

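The stricter filters, pseudocounts and floor in this part were chosen after seeing the data. The planned versions that read background from Plasmodium probe sets, and the gene set alternatives, were not run. All 7 changed probe sets kept their direction under each of the 17 alternatives that tested them (6 of the 7 were tested with the filter at the 80th percentile). Filter, block and variance settings keep the same fold change. The groups did not overlap at the 7, so only quantile normalization and median centring could reverse a direction. The count stayed at 7 with no filter and with median centring, the same 7 probe sets, and was 6 with quantile normalization and 6 with the filter at the 60th percentile. The filter at the 80th percentile left 5, with 2 higher. Without a variance trend limma called 0 (0 higher, 0 lower; 665 at an unadjusted p under 0.05), and without any moderation of the variance also 0 (0 higher, 0 lower; 658 unadjusted), with smallest adjusted p of 0.40 and 0.43. A pseudocount of 16 gave 10 calls (7 higher) and one of 64 gave 22 (17 higher, 5 lower), and the floor at the filter signal gave 33 (27 higher, 6 lower); these settings shrink the scatter of dim signals by construction. Leaving out 1 array gave 2 to 105 calls, 1 to 91 higher and 1 to 14 lower, with the 105 coming from the fit without BSA replicate 3. Of the named probe sets, Ag.3R.578.1_CDS_a_at stayed past the threshold in 15 of 17 alternatives (adjusted p 1.7e-05 to 0.68), Ag.3R.795.0_CDS_at in 13 of 17, Ag.2R.2566.0_CDS_at in 13 of 16 and Ag.2L.205.0_CDS_at in 7 of 17. With the replicate number as a block, 79 probe sets passed (63 higher, 16 lower), including all 7. Deviations of same-numbered arrays from their group means correlated at 0.11, 0.05 and 0.09 over all tested probe sets. In those above the median signal they correlated at 0.13, 0.13 and 0.19. Each array correlated best with its own number. The deviations within a group cancel by construction, so these matches are not independent of each other. The limit of 0.1 was not met over the tested set and was met above the median signal. The array medians also rose from replicate 1 to replicate 3 with both meals. The 2% trimmed means fell in the same order (216.4, 211.2 and 208.3 after BSA, 216.7, 212.8 and 206.2 with E. coli). These orders go with a pairing by number, but no label explains the numbers, so whether they pair the pools stays open. Signal limits precision: the median 95% half-width of a log2 fold change was 0.64 in the brightest tertile and 2.01 in the dimmest.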

Other observations

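The tests on pairs of probe sets, on other splits of the arrays and on BSA replicate 3 were chosen after the arrays had been compared. The IDs carry the name of a chromosome arm. The 7 changed probe sets comprised 3 with 2R, 2 with 2L and 2 with 3R. Of the tested probe sets with UNKN in place of an arm, 5.93% had an unadjusted p under 0.05 (36 higher, 17 lower of 894), a lower share than among the rest (two-sided Fisher's exact test, adjusted p = 0.032 over 6 ID groups). That test counts probe sets as independent although all were read on the same 6 arrays, so its p does not measure spread between pools. The UNKN probe sets had a median signal of 82.3, the dimmest of the 6 groups. No other group differed after adjustment, with shares from 6.36% for X to 9.53% for 3L. Probe sets with UTR in their ID were brighter (median signal 569.9) than those with CDS (median signal 104.3). Their median log2 fold changes were -0.06 and 0.07, and -0.05 and 0.02 after quantile normalization.

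Probe sets that share an ID number moved together more than chance partners did. Over 379 such pairs with a geometric mean signal above 256, the log2 fold changes correlated with r = 0.42 (Spearman's rho = 0.45). In 10000 shuffles of partners within bins of like signal, r reached at most 0.22 (permutation p = 0.0001, the smallest these shuffles can give). The correlation is across pairs of probe sets, which are not independent replicates. It is consistent with pairs that read 1 locus, a hypothesis, since no table here ties the IDs to genes and paired probe sets can share probes. The signs of the 2 members were alike in 63.6% of pairs.

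BSA replicate 3 lay towards the E. coli arrays in many bright probe sets. Bright here means a geometric mean signal above 256 (3040 probe sets). There, the difference of BSA replicate 3 from BSA replicate 1 correlated at 0.53 with that of the E. coli mean from BSA replicate 2. With the BSA arrays exchanged the correlation was 0.62. Each pair of differences shares no array of the BSA group. The same measure for BSA replicate 1 against BSA replicate 2 was 0.15. It is not a separate comparison, because its covariance is fixed by algebra as the difference of the covariances of the other 2. Over all 10133 tested probe sets the values were lower, at 0.11 and 0.16 against 0.05. For the 105 probe sets called without it, BSA replicate 3 sat on the log2 scale at a median of 82.6% of the way from the other BSA arrays to the E. coli mean at the 91 higher probe sets, and at 41.9% (quartiles 29.7% and 71.5%) at the 14 lower ones. On a log2 scale, 1 mixing share of linear signals would also place rises further along than falls. The difference between 82.6% and 41.9% therefore does not show that this array shared the rises more than the falls. BSA replicate 3 was not alone in crossing the groups. Among the bright probe sets E. coli replicate 2 correlated better with each BSA array (0.924 to 0.954) than with E. coli replicate 1 (0.912).

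Scaling of the arrays was argued against, because the smaller correlation was still 0.50 after quantile normalization. A difference in RNA integrity or labelling length was predicted to lose the correlation in probe sets with UTR in their ID, taken to lie nearest the labelled 3' end. The smaller correlation there was 0.70, against the prediction. The test cannot decide the question, because the IDs do not say which end of the transcript is read. Those probe sets were also brighter (median signal 569.9, against 104.3 with CDS), and the correlation was higher among bright probe sets. RNA integrity stays open as a whole or partial cause. The Gapdh 3' to middle ratio of BSA replicate 3 was 5.51 against 9.19 and 9.38 on the other BSA arrays. E. coli replicates 1 and 2 lay on the same side (4.43 and 7.84), with E. coli replicate 3 on the other (10.8). Actin showed no such shift: the 3' to middle ratio of BSA replicate 3 was 4.41, against 4.57 and 5.10. Its actin 3' to 5' ratio was the highest of the BSA arrays. A fixed share of E. coli-fed material in that pool could not be told apart from other causes: 1 mixing share of 63.2% left 4 of the 105 probe sets (3.81%, exact 95% interval 1.05% to 9.47%) more than 3 SD away, and the interval spans the 5% set as the limit. Of those 4, 3 lay nearer to the other BSA arrays than that share allows. An unrecorded batch, or a difference in BSA replicates 1 and 2 and not in replicate 3, stays open and untested because no label gives a batch, and no biological explanation was tested.

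The split of the arrays by meal gave 7 calls, and the highest count among the other splits of 3 against 3 was 0. With 1 of 10 splits reaching 7, the splits are too few for a share under 0.05.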
